A study of Homo sapiens with 30 samples.

How the data were processed

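The series measured guide abundance by sequencing in 30 libraries from pooled CRISPR-Cas9 knockout screens in HCT116, a human colorectal carcinoma line, carrying the Brunello library of guides. Per the labels there were 3 screens, each with 5 cell populations and 2 replicates of each population. In the N1m screen the cells received lipid nanoparticles with EGFP mRNA made with N1m-pseudouridine, a modified form of uridine. In the UTP screen the mRNA is taken to be the unmodified form, since the series contrasts mRNA with and without the modification. In the Stable screen the cells expressed GFP stably, as the cellular control. The populations were the dimmest 2.5% of cells by GFP (bottom outer bin), the next band up to 5% (bottom second bin), the matching brightest bands (top outer and top second bins), and unsorted cells. Whether the replicates came from separate cultures or sorts is not stated, so the p-values may measure technical spread in part.

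The deposited values are a signal made by the authors. The unit was settled from the values once they were read: every library sums to 1 common total plus the number of guides, the minimum is exactly 1, and each value less 1 is a whole multiple of 1 step per library within a tolerance of 0.001. They were therefore read as RPM, reads scaled to a common library total per M reads, with 1 added, not rounded. The submitters' processing notes name cutadapt and Bowtie2 without versions or settings, and the guide reference and the mismatch setting are not stated. The added 1 was removed, and whole reads were recovered from the step. The table held 77441 guides, of which 1000 were non-targeting, and 19114 gene names. Current symbols were looked up by name in RefSeq (GRCh38.p14): 17852 were current as given, 1135 matched through 1 synonym, and 127 did not match or matched several. Genes are named as in the table; guide positions in the genome were not analysed here. Reads without molecular identifiers are not independent molecules, so read depths do not give the number of molecules counted.

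The following choices were made before the data were examined. Guides with a mean of at least 1.0295 RPM were kept, which is 0.1 of the median RPM of 10.3 over all guides and libraries. That kept 75344 guides (97.4%), and 19026 genes with at least 2 kept guides were tested. A gene's value in a library was the mean over its guides of log2(RPM + 1.0295). Limma with a trended prior was fitted to the 8 sorted libraries of a screen, with 1 group per bin. The contrast was the bottom outer bin minus the top outer bin, so a positive log2 difference means that knockout cells were enriched among GFP-low cells. The second bins were compared the same way. Each outer bin was compared with unsorted cells using 10 libraries of the screen and array weights for sorted and unsorted libraries. Differences between screens were tested as interactions in a fit of all 24 sorted libraries with array weights by screen. Each source of GFP had its own screen, so an interaction cannot tell the source from other differences between the screens. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, with 0.05 as the threshold. Errors on log2 differences are standard errors from limma; errors on RPM are SDs of 2 libraries.

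Controls were 250 random sets of 4 non-targeting guides and 368 olfactory receptor genes, which colon cells are not known to need. The non-targeting guides had a median of 27.5 RPM in unsorted cells against 10.6 for targeting guides and 11.3 for guides to olfactory receptor genes. Their sets are therefore less noisy than genes, and the olfactory receptor genes are the control at a matched level.

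A set of 26 gene lists fixed beforehand was tested by camera in limma with a preset correlation of 0.01, in the outer-bin contrast of each screen and in the interactions, with Benjamini-Hochberg adjustment over all 156 tests. Camera with an estimated correlation was run beside it. The lists covered heparan sulfate synthesis, chondroitin synthesis, the COG complex with Golgi transport, the V-ATPase with its assembly factors, endosome maturation, retromer with commander and ESCRT, endocytic coat and actin, lipid uptake and sterol regulation, the TRIM25 and ZAP axis, RNA sensing, interferon receptor signalling, antiviral RNA effectors, deadenylation, decapping, exosome and SKI, nonsense-mediated decay, ribosome quality control, cytosolic ribosomal proteins, translation initiation, mTORC1 activators, mTORC1 inhibitors, the integrated stress response, the proteasome, mediator with transcription elongation, transgene silencing, and olfactory receptors.

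Genes were named by a rule: in each screen, the 10 largest positive and 10 largest negative outer-bin differences among genes past the threshold with the same sign in both replicates and in at least 3 guides; the 5 largest per direction in each interaction, without the guide condition; the up to 4 members of a list with the smallest p; and, whatever their result, TRIM25, ZC3HAV1, KHNYN, N4BP1, DDX58, IFIH1, MAVS, EIF2AK2, EXT1, NDST1, SLC35B2, B4GALT7, ATP6V0C and ATP6AP1. Another 2 genes fixed by the rule stayed in the fits and lists and are not reported here. The fixed genes that missed the threshold are given in the outer bins, and of these TRIM25 alone in the interactions.

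Alternatives tried were a smaller and a larger pseudocount, no guide filter and a stricter one, the median over guides, centring on the non-targeting guides, scaling to equal totals (which can move nothing in RPM and is not counted), a replicate block, robust rank aggregation of guides, a slope over the 4 ordered bins, fits of fewer or more libraries, no array weights, and leaving out each library in turn. Summed whole reads with limma voom, a slope in the interactions, and leaving out the UTP library with the most guides at 0 were added after the data had been seen. The closing section gives their effect. The tests were also run on simulated data with known changes, at a pair of settings for the number of cells per guide; the report gives the noisier setting, which was chosen after the replicate spread had been seen. R 4.3.3, limma 3.58.1 and the data.table package, version 1.17.8, were used.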

Results

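The data were guide abundances from 30 sequencing libraries of HCT116 cells carrying a pooled knockout library. There were 3 screens, of mRNA with the modification (N1m), of mRNA without it (UTP) and of cells with stable GFP (Stable), and each had 4 sorted GFP bins and unsorted cells with 2 replicates. Total reads, in M (mega) reads, ranged from 31.2 to 32.7 M in the sorted N1m libraries, from 40.5 to 41.8 M in the sorted UTP libraries and from 31.4 to 32.9 M in the sorted Stable libraries. The unsorted libraries held 31.2 to 31.9 M reads in N1m, 41.5 to 41.7 M in UTP and 31.1 to 31.3 M in Stable. Guides with 0 reads made up 4.04% to 10.9% of a sorted library and 1.21% to 1.60% of an unsorted one. Pearson correlations between replicates, across genes, were 0.557 to 0.677 in the sorted bins and 0.939 to 0.944 in unsorted cells; genes are not independent replicates. In simulated data limma recovered 13.6%, 60.6% and 98.4% of genes with a true log2 difference of 1, 2 and 3, and it called 4 unchanged genes. The simulated bottom outer bin had a replicate correlation of 0.675, so it was less noisy than those of N1m, UTP and Stable at 0.560, 0.564 and 0.591.

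The outer bins of the N1m screen asked which knockouts lower or raise GFP made from delivered modified mRNA. Of 19026 genes, 21 passed the threshold, 21 with guides enriched in GFP-low cells and 0 in the other direction, where limma gave 683 genes at an unadjusted p under 0.05. Both directions together held 5.54% of genes at that p, about the share that chance gives, and the median difference of all genes was -0.086. The largest difference was that of ATP6AP1, an accessory subunit of the V-ATPase, the proton pump that acidifies endosomes and lysosomes. Its guides rose by 4.55 ± 0.58 on the log2 scale (adjusted p 9.0e-08, 4 of 4 guides), from 2.82 ± 0.622 RPM in the top bin to 63.5 ± 8.90 RPM in the bottom bin (SD, n = 2), with 6.10 RPM in unsorted cells. ATP6V0D1, a subunit of the membrane sector of the pump, rose by 4.08 ± 0.46 (adjusted p 9.8e-10, 3 guides). ATP6V0C, which forms the proton-carrying ring, rose by 3.84 ± 0.38 (adjusted p 1.8e-11), from 10.5 ± 3.54 to 127 ± 69.4 RPM (SD, n = 2). ATP6V0B rose by 3.19, and ATP6V1B2 and ATP6V1A of the catalytic sector rose by 2.93 and 2.80. Of the 32 V-ATPase genes measured, 8 passed, 11 passed when adjusted over the list alone, and 26 lay above 0, with a median of 0.66. The camera test of this list gave an adjusted p of 4.2e-25, and of 0.0351 with an estimated correlation.

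Genes that build heparan sulfate, a cell-surface sugar chain, formed another group in the N1m screen. NDST1, which sulfates the chain, rose by 2.43 ± 0.26 (adjusted p 3.8e-10), from 15.5 to 77.5 RPM. B4GALT7, which makes the linker between chain and protein, rose by 2.88 ± 0.56 (adjusted p 0.0024), and SLC35B2, which carries the sulfate donor into the Golgi, rose by 2.58 ± 0.45 (adjusted p 3.9e-04). The chain polymerases EXT2 and EXT1 rose by 2.31 and 2.14, and EXTL3, which starts the chain, rose by 2.19. Of the 25 genes of this list, 6 passed, 6 passed when adjusted over the list alone, and the median was 0.67 (camera adjusted p 1.9e-14, and 0.0527 with an estimated correlation). SLC39A9, a zinc transporter of the Golgi, rose by 3.05 ± 0.48 (adjusted p 3.4e-05). C3orf58, now named DIPK2A, a Golgi protein, rose by 2.69, and TRAPPC4, a vesicle-tethering subunit, rose by 2.64. Of 21 genes of the COG and Golgi list, 1 passed, 2 passed when adjusted over the list alone, and the median was 0.56 (camera adjusted p 3.2e-07, and 0.271 with an estimated correlation). The genes TRAPPC11, ATP6V1G1, ATP6AP2, PREB, CAMLG and TM9SF3, named after their values were seen, rose by 1.67 to 2.54. The other 23 lists had adjusted p-values from 0.163 to 0.989. The number of genes past the threshold was 12 without top outer replicate 2 and 13 with a pseudocount of 1/100 of the median.

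The outer bins of the UTP screen asked the same of the mRNA without the modification. Here 15 genes passed, 14 enriched in GFP-low cells and 1 in GFP-high cells. ATP6AP1 rose by 3.99 ± 0.52 (adjusted p 3.6e-06), from 4.17 RPM (6.28 and 2.05 in the replicates) to 60.8 RPM (69.3 and 52.3). ATP6V1B2 rose by 3.53 ± 0.60 (adjusted p 6.4e-04), ATP6V0C by 3.42 ± 0.36 (adjusted p 2.0e-08) and ATP6V0D1 by 3.15 ± 0.41. ATP6AP2, another accessory subunit, rose by 3.14 ± 0.48 (adjusted p 8.2e-05), and ATP6V1A and ATP6V1G1 rose by 2.82 and 2.79. Of the 32 V-ATPase genes, 8 passed, 13 passed when adjusted over the list alone, and the median was 1.01 (camera adjusted p 4.6e-28, and 0.0251 with an estimated correlation). Among heparan sulfate genes, EXTL3 rose by 2.82 ± 0.42 (adjusted p 6.5e-05), SLC35B2 by 2.50 ± 0.42 (adjusted p 6.4e-04) and NDST1 by 1.92 ± 0.27 (adjusted p 2.0e-05), while B4GALT7 at 2.64 (adjusted p 0.0863) and EXT1 at 1.97 (adjusted p 0.594) missed the threshold. Of the 25 genes of that list, 3 passed and 7 passed when adjusted over the list alone, with a median of 0.61 (camera adjusted p 9.6e-16, and 0.0656 with an estimated correlation).

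SRPR, now SRPRA, a subunit of the receptor that brings secretory ribosomes to the endoplasmic reticulum, rose by 2.37 ± 0.41 in the UTP screen (adjusted p 7.4e-04), and COG3, a subunit of the Golgi tether COG, rose by 2.26 ± 0.44 (adjusted p 0.0073). Of the 21 COG and Golgi genes, 1 passed and 4 passed when adjusted over the list alone, with a median of 0.54 (camera adjusted p 1.0e-09, and 0.215 with an estimated correlation). ATP6V0B and CAMLG, named after their values were seen, rose by 2.26 and 1.74. FZR1, an activator of the cell-cycle ubiquitin ligase APC/C, fell by 1.86 ± 0.41 (adjusted p 0.0443), from 36.2 RPM in the top bin to 16.2 RPM in the bottom bin. The call on FZR1 was lost under 6 of 11 alternatives, one of which was a pseudocount of 1/100 of the median, where the whole count was 8. It was also lost without each of the 4 outer libraries in turn, and its difference ranged from -2.65 to -1.16 over these settings. The count was 23 without bottom outer replicate 2. Apart from the TRIM25 and ZAP list given with TRIM25, the other 22 lists had adjusted p-values from 0.344 to 0.989.

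TRIM25, an RNA-binding ubiquitin ligase of the antiviral response that the series title names, had its highest guide level in GFP-high cells of the UTP screen, in a difference that missed the threshold. Its log2 difference was -2.69 ± 0.62 (adjusted p 0.0850), with 4 of 4 guides negative. Its guides were at 40.1 ± 1.70 RPM in the top outer bin, 19.6 ± 0.930 in the top second bin, 9.15 ± 0.0988 in unsorted cells, 5.86 ± 2.59 in the bottom second bin and 4.88 ± 4.68 in the bottom outer bin (SD, n = 2). The replicates of the bottom outer bin read 1.57 and 8.19 RPM. A slope over the 4 bins was -3.01 ± 0.59 and passed (adjusted p 0.0056). TRIM25 also passed with the replicate block (adjusted p 0.0276) and without bottom outer replicate 2 (adjusted p 0.0042), while over all alternatives its adjusted p reached 0.9999, without top outer replicate 1. In the N1m screen the difference of TRIM25 was -0.11 ± 0.63, with 8.59 ± 1.66 RPM in the bottom outer bin and 10.4 ± 0.625 RPM in the top outer bin (SD, n = 2). In the Stable screen it was -1.83 ± 0.60 (adjusted p 0.521), with 3.13 ± 0.335 and 9.47 ± 0.707 RPM (SD, n = 2).

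The interaction of the UTP and N1m contrasts asked whether a knockout acts differently on unmodified mRNA. It cannot tell the modification from other differences between these screens. For TRIM25 it was -2.58 ± 0.89, with p 0.0045 before adjustment and 0.9998 after it. Of 19026 genes, 1 passed, TYW1B, a near copy of the tRNA-modification gene TYW1, with 2 kept guides and -5.42 ± 0.94 (adjusted p 0.0019). Its levels in the bottom and top outer bins were 9.96 and 1.08 RPM in N1m and 0.676 and 12.4 RPM in UTP. The replicates read 2.12 and 0.0320 RPM in the N1m top bin and 0.0481 and 1.30 RPM in the UTP bottom bin. Over the alternatives and with single libraries left out, its difference ranged from -9.23 to -2.70, so its size was poorly measured. The count was 0 without N1m top outer replicate 2, without UTP bottom outer replicate 1, without UTP top outer replicate 2, and with a pseudocount of 1/100 of the median. None of the 26 lists passed by camera, with a lowest adjusted p of 0.480. Recovery was simulated for the interaction of N1m and Stable, not for this one, with the same noise, less than that of the data. There 6.06%, 28.8% and 85.9% of true differences of 1, 2 and 3 were recovered.

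**Figure D1:**
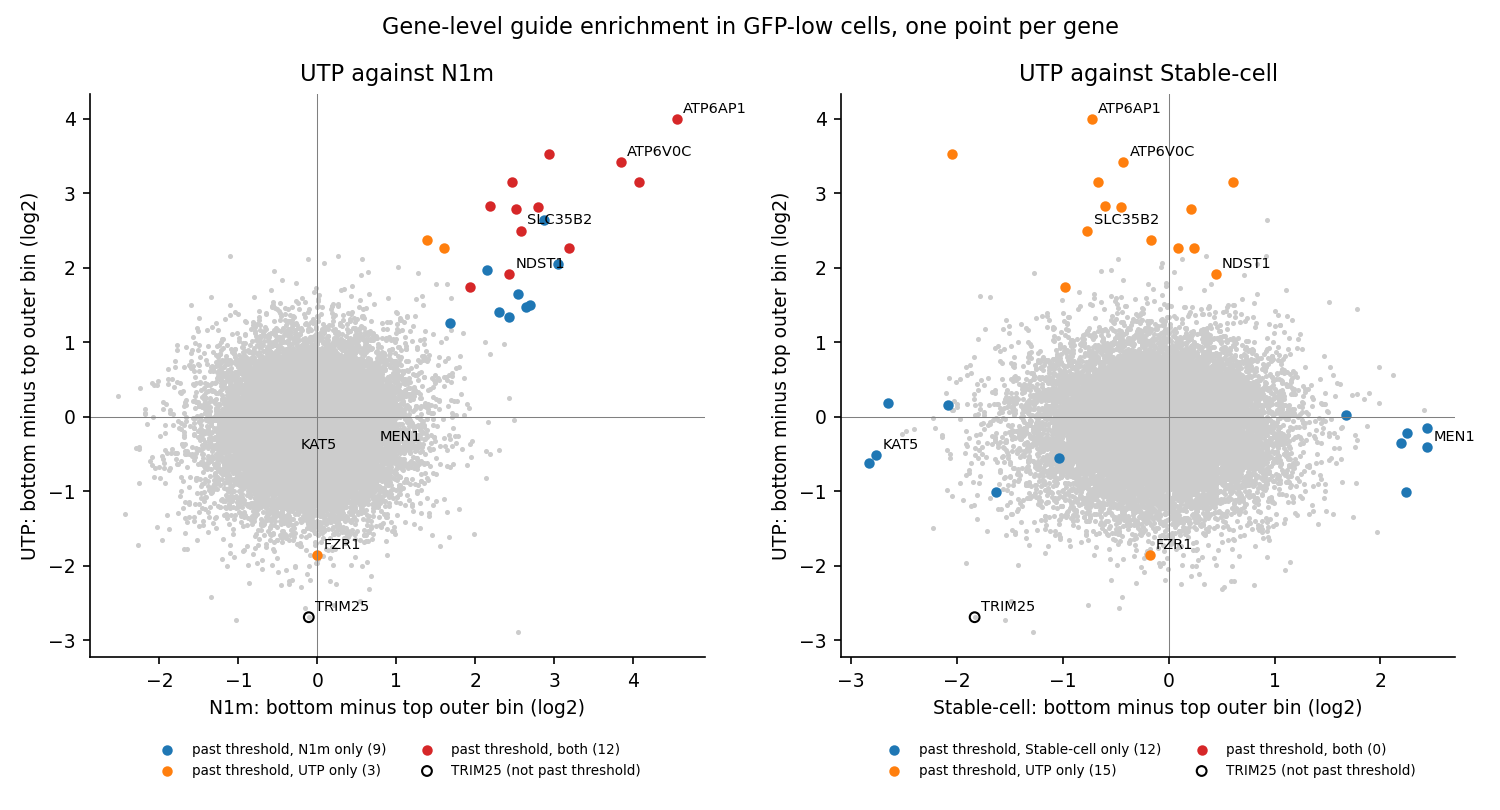
Log2 difference between the bottom and top outer GFP bins for each gene, UTP against N1m and UTP against Stable, with genes past the threshold in colour. The 12 genes past it in both mRNA screens lie at the upper right, 0 genes pass in both UTP and Stable, and TRIM25 lies at -2.69 in UTP.

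**Figure D2:**
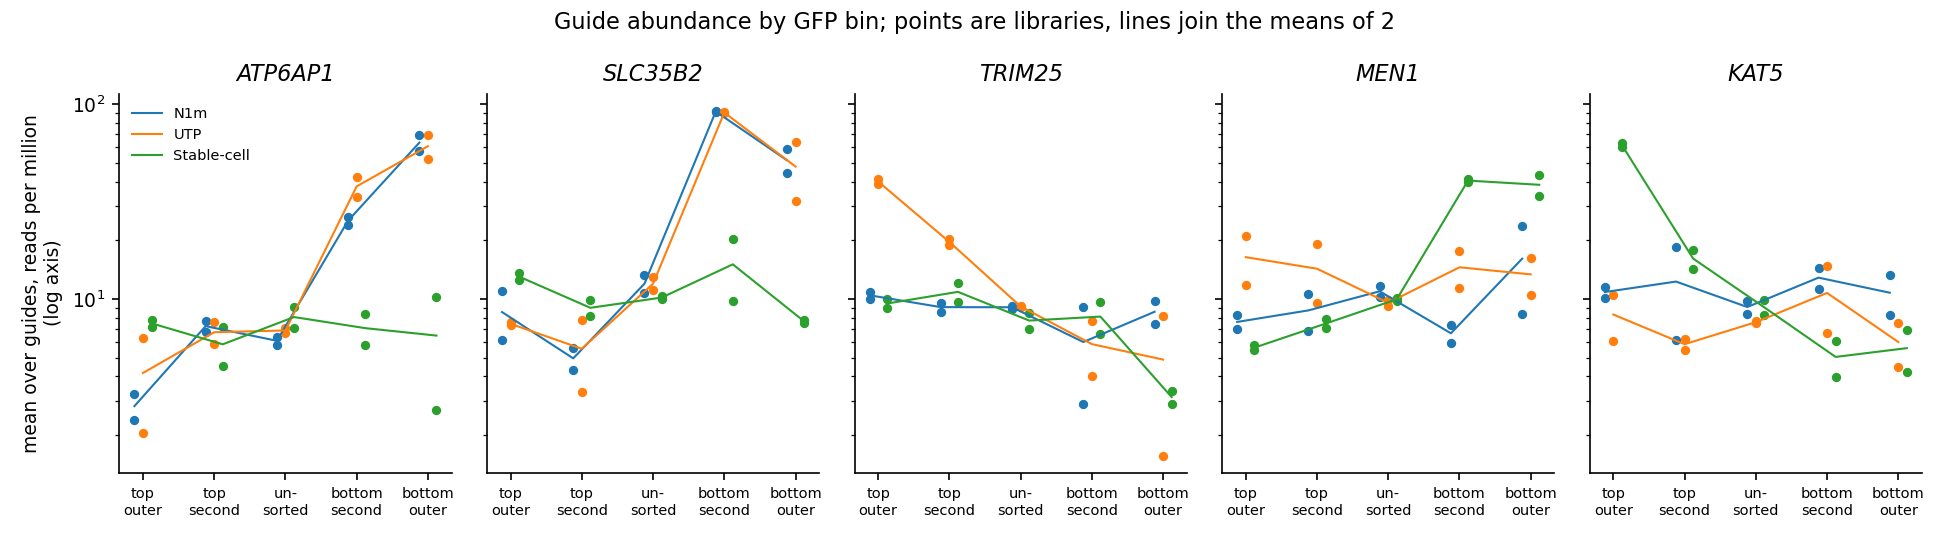
Guide abundance in RPM (log axis) of 5 genes in the ordered GFP bins of each screen, with points for the 2 libraries and lines through their means. TRIM25 in UTP falls from 40.1 RPM in the top outer bin to 4.88 RPM in the bottom outer bin.

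Other genes of RNA sensing and decay, fixed for report beforehand, did not pass in any screen. ZC3HAV1, the zinc-finger antiviral protein that works with TRIM25, had 0.35 in N1m, -0.69 in UTP and -0.03 in Stable. Its cofactors KHNYN and N4BP1 had 0.32 and -1.11 in N1m and -0.00 and -1.22 in UTP. The cytosolic sensors DDX58 (now RIGI) and IFIH1 had -1.14 and -0.77 in N1m and -1.07 and -1.05 in UTP, and their adaptor MAVS had -0.55 and -0.70. The kinase EIF2AK2 had 0.56 and -1.03 in N1m and UTP in turn. In Stable the values were -0.79 for KHNYN, -0.37 for N4BP1, 0.39 for DDX58, 0.20 for IFIH1, 0.54 for MAVS and 0.40 for EIF2AK2. The list of 12 genes around TRIM25 and ZAP had a median of -0.64 in UTP (camera adjusted p 0.0073, and 0.367 with an estimated correlation). In it 0 genes passed by limma and 1, TRIM25, passed when adjusted over the list alone; since the title names TRIM25, that list is not independent evidence. Its adjusted p was 0.194 without UTP bottom outer replicate 1, and 0.134 with a pseudocount of 1/100 of the median.

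The outcome of the mRNA screens was compared across genes. Of the genes enriched in GFP-low cells, 12 passed in both N1m and UTP where 0.0155 would be shared by chance (Fisher's exact p 5.7e-36, one-sided). They were ATP6AP1, ATP6AP2, ATP6V0B, ATP6V0C, ATP6V0D1, ATP6V1A, ATP6V1B2, ATP6V1G1, CAMLG, EXTL3, NDST1 and SLC35B2. All 21 genes called in N1m lay above 0 in UTP, and all 15 called in UTP had the same sign in N1m. Over all 19026 genes the Pearson correlation of the contrasts was 0.0578, across genes that are not independent replicates.

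The Stable screen asked which knockouts change GFP made from a gene of the cell. There 12 genes passed, 6 in each direction, and 0 of them passed in either mRNA screen. MEN1, which anchors a histone methyltransferase complex, rose by 2.44 ± 0.45 in GFP-low cells (adjusted p 0.0025), from 5.62 ± 0.256 to 38.6 ± 6.98 RPM (SD, n = 2). The methyltransferases KMT2A and KMT2C rose by 2.44 ± 0.50 (adjusted p 0.0098) and 1.67 ± 0.33 (adjusted p 0.0068). SMARCD1 and BRD9, subunits of BAF chromatin remodellers, rose by 2.25 ± 0.40 (adjusted p 0.0024) and 2.20 ± 0.46 (adjusted p 0.0160). MED12 of the mediator rose by 2.24 ± 0.48 (adjusted p 0.0225). Of 42 genes of the mediator and elongation list, 1 passed, 4 passed when adjusted over the list alone and 28 lay above 0, with a median of 0.33 (camera adjusted p 1.1e-05, and 0.215 with an estimated correlation). The other 25 lists had adjusted p-values from 0.0717 to 0.989.

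Among genes enriched in GFP-high cells of the Stable screen, the acetyltransferase KAT5 fell by 2.76 ± 0.53 (adjusted p 0.0044), from 61.7 ± 2.05 RPM in the top bin to 5.59 ± 1.91 RPM in the bottom bin (SD, n = 2). The remodeller CHD4 fell by 2.65 ± 0.53 (adjusted p 0.0070) and the methyltransferase SETD2 fell by 2.08 ± 0.47 (adjusted p 0.0369). LYRM4, of iron-sulfur cluster assembly, and ELP5, of the Elongator complex, fell by 1.63 and 1.03, each with adjusted p 0.0433. FRG2C, with 2 guides and chosen after its values were seen, had 0.0310 and 0 RPM in the bottom bin and 6.64 RPM in the top bin, so its fitted difference is no measure of size. The count was 0 without top outer replicate 1, 7 without bottom outer replicate 1, 4 without top outer replicate 2, 5 without bottom outer replicate 2 and 0 with a pseudocount of 1/100 of the median. The genes of the mRNA screens did not pass here: ATP6AP1 had -0.72, ATP6V0C -0.43, SLC35B2 -0.77, EXT1 -0.54, NDST1 0.44 and B4GALT7 0.92.

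Interactions with the Stable screen asked which effects belong to delivered mRNA. Between UTP and Stable 11 genes passed, of which ATP6V1B2 differed by 5.57 ± 0.86 (adjusted p 3.6e-05), ATP6AP1 by 4.72, ATP6V0C by 3.85, ATP6V0D1 by 3.82 and EXTL3 by 3.43. PCBP2, an RNA-binding protein, differed by -3.51 ± 0.75 (adjusted p 0.0196), with a range from -5.17 to -2.07 over the alternatives and single libraries left out. Its call was kept under 6 of 9 alternatives but lost without each outer library of UTP and Stable in turn. Between N1m and Stable 11 genes passed, of which ATP6AP1 differed by 5.28 ± 0.82, ATP6V1B2 by 4.98, ATP6V0D1 by 4.74, ATP6V0C by 4.27 and SLC35B2 by 3.35. ATP6V1B2 had -2.04 in Stable itself (adjusted p 0.429), where the replicates of the bottom bin read 0.00775 and 1.84 RPM. Over the alternatives and with single libraries left out, its difference from Stable ranged from 2.93 to 9.59 in UTP and from 2.72 to 8.40 in N1m, so its size was poorly measured. The V-ATPase list passed in both, with medians of 1.17 for UTP (camera adjusted p 1.9e-14) and 0.90 for N1m (camera adjusted p 9.3e-14), as did the heparan sulfate list, with medians of 0.88 (adjusted p 8.3e-09) and 0.65 (adjusted p 1.4e-07). These results held with an estimated correlation, at adjusted p 0.0036 for the V-ATPase list in both and 0.0115 and 0.0168 for the heparan sulfate list. Adjusted over the list alone, 10 and 9 V-ATPase genes and 5 and 6 heparan sulfate genes passed, against 5 and 5 and 2 and 3 over all genes.

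The COG and Golgi list passed in both interactions with Stable (medians 0.68 and 0.65, camera adjusted p 3.9e-04 and 0.0068), and the mediator list had medians of -0.56 and -0.66 (adjusted p 5.2e-04 and 0.0011). The TRIM25 and ZAP list had -0.81 between UTP and Stable (adjusted p 0.0323). None of these held with an estimated correlation, where adjusted p-values were 0.207 or higher. For TRIM25 itself the difference was -0.86 between UTP and Stable and 1.73 between N1m and Stable, with adjusted p-values of 0.996 and 0.941. The remaining lists had adjusted p-values from 0.103 in UTP and from 0.163 in N1m. The number of genes between UTP and Stable was 3 without UTP top outer replicate 2, 5 without UTP top outer replicate 1, UTP bottom outer replicate 1 or Stable top outer replicate 2, 6 without UTP bottom outer replicate 2, and 7 without Stable top or bottom outer replicate 1. Between N1m and Stable it was 4 without Stable top outer replicate 2, 5 without N1m bottom outer replicate 1, 6 without N1m top outer replicate 2, 7 without Stable top or bottom outer replicate 1, and 17 without Stable bottom outer replicate 2.

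**Figure D3:**
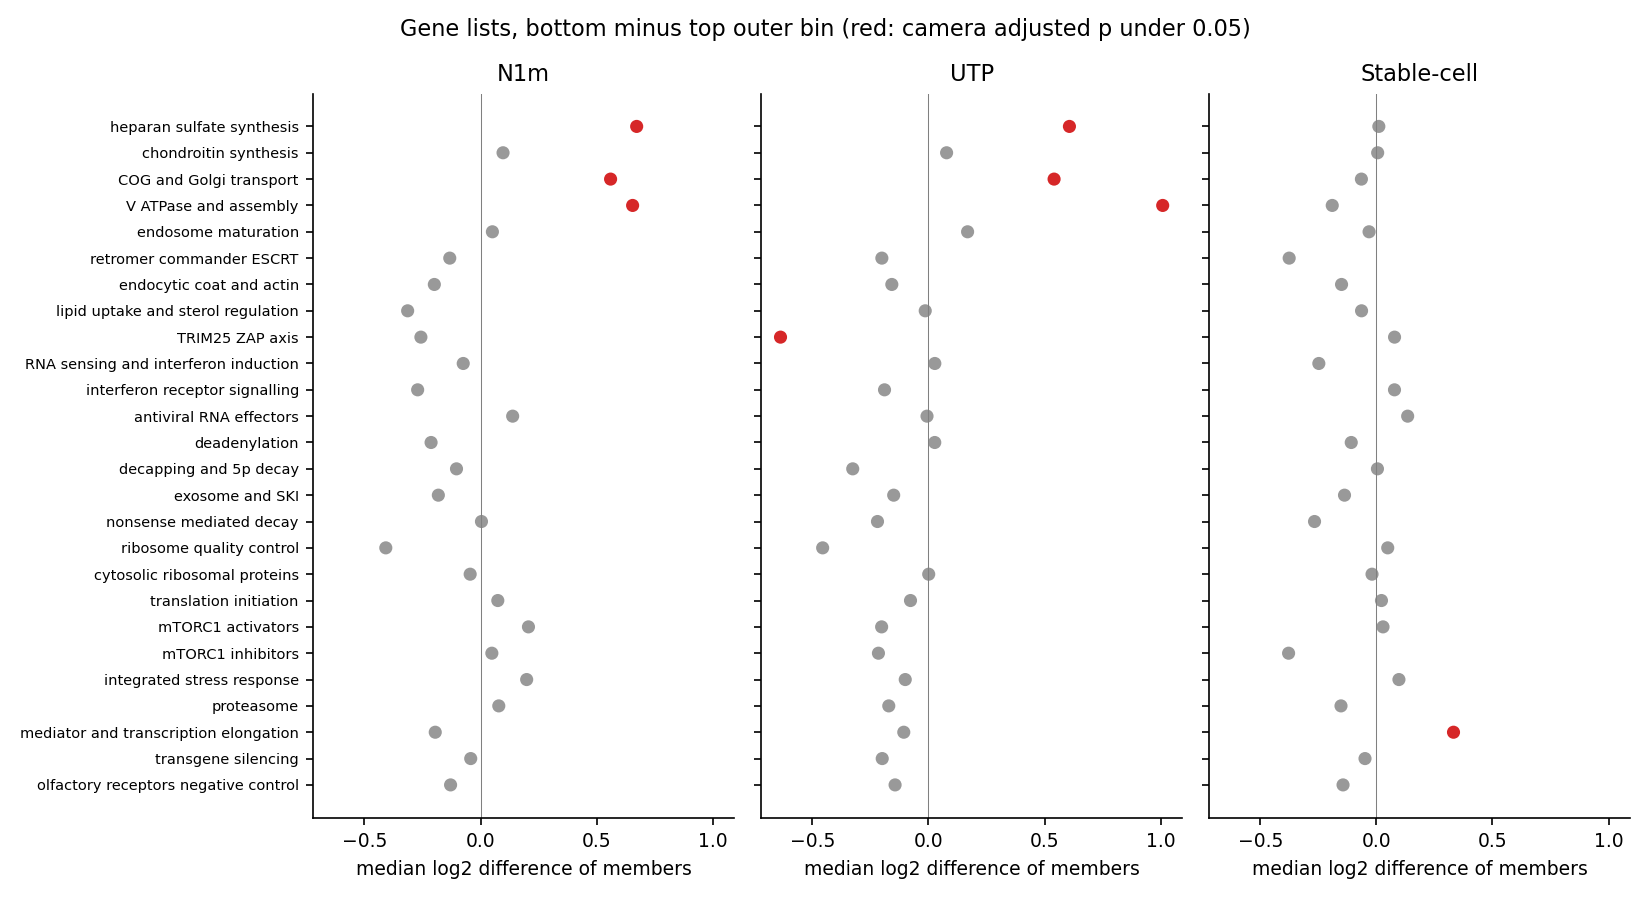
Median log2 difference (bottom minus top outer bin) of the members of each of the 26 gene lists in each screen, with red points for lists past the threshold by camera. The V-ATPase list has medians of 0.66 in N1m and 1.01 in UTP, and the mediator list has 0.33 in Stable.

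The second bins, sorted from the same cells, were compared next. In N1m 18 genes passed (18 higher in GFP-low cells), and of the 21 called in the outer bins 12 passed here and 21 had the same sign. SLC35B2 rose by 4.44 ± 0.45, more than in the outer bins, from 4.95 to 91.7 RPM, and B4GALT7 rose by 4.29. In UTP 19 genes passed, 18 higher and 1 lower in GFP-low cells, and SLC35B2 rose by 4.26 ± 0.42, B4GALT7 by 3.62, EXT1 by 2.64 and NDST1 by 2.52. In Stable 18 genes passed, and SMARCD1 rose by 3.35 ± 0.40, BRD9 by 2.78 and MEN1 by 2.56. TRIM25 had -0.88 in N1m, -1.98 in UTP (adjusted p 0.580) and -0.78 in Stable. The UTP count was 96 without bottom second replicate 2, 8 without top second replicate 1, 10 without top second replicate 2 and 11 without bottom second replicate 1. The N1m count was 7 and 9 without bottom second replicate 2 and 1, and the Stable count 7 and 11 without top second replicate 1 and 2.

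Outer bins were also set against unsorted cells. In the top bin 7 genes passed in N1m, all lower, and 2 in Stable, where KAT5 rose by 1.96 ± 0.39 (adjusted p 0.0172). In UTP 0 passed by limma. There 1022 genes (5.37%) had an unadjusted p under 0.05, about the share that chance gives, and 1000 of these were lower. TRIM25 in the top bin of UTP had 1.41 (p 0.0020, adjusted p 0.777). In the bottom bin 15 genes rose in N1m, led by ATP6AP1 at 3.21, 10 in UTP, where ATP6AP1 rose by 2.97, and 2 in Stable, MEN1 at 1.71 and KMT2A at 1.68. Lower calls in the bottom bin numbered 90, 61 and 93 in N1m, UTP and Stable, but 0 in each with no array weights or without either unsorted library. They came on top of a median shift of all genes of -0.33, -0.33 and -0.30, against -0.20, -0.21 and -0.16 for the non-targeting sets. Apart from the 0 in UTP, these counts moved when 1 library was left out. Without 1 unsorted library the bottom-bin count was 3 (replicate 1) or 1 (replicate 2) in N1m, 1 or 0 in UTP and 0 in Stable, and the top-bin count was 0 in N1m and Stable. Without bottom outer replicate 1 the bottom-bin count was 199 in N1m and 20 in UTP, and without replicate 2 it was 23 and 263; it was 155 in UTP without bottom second replicate 1. The N1m top-bin count was 0 without top outer replicate 2 and 11 without replicate 1, and the Stable one was 0 without either.

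Controls were read in the same contrasts. By limma, 0 of 250 non-targeting sets passed in any contrast, with 2%, 4.4% and 4.8% at an unadjusted p under 0.05 in the outer bins of N1m, UTP and Stable. Of 368 olfactory receptor genes, 0 passed in the outer and second bins, in the interactions and against unsorted cells, apart from 3 in UTP and 3 in Stable in the bottom bin against unsorted cells. Their share at an unadjusted p under 0.05 was 4.08%, 4.89% and 4.89% in the outer bins. In the bottom bin against unsorted cells the shares were higher, at 11.6%, 10.8% and 14% of the non-targeting sets and 17.7%, 14.4% and 15.8% of the olfactory receptor genes, so p-values in that contrast were poorly calibrated. In the second bins and the top bin against unsorted cells the shares ranged from 4.4% to 7.6% and from 3.80% to 8.42%, and in the interactions they were 3.6% and 3.26% to 5.71%.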

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

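The tests of TYW1 and of random guide pairs were planned before their results were seen; the test of TYW1B against guides of the same level was added after that of the non-targeting pairs had been read.

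The results here are differences between screens in the outer-bin contrast, each past the threshold in limma's interaction test. Between the mRNA screens this was TYW1B alone, with -5.42. Between UTP and Stable the V-ATPase genes were higher in UTP: ATP6V1B2 by 5.57, ATP6AP1 by 4.72, ATP6V0C by 3.85, ATP6V0D1 by 3.82 and ATP6V1A by 3.27. The heparan sulfate genes EXTL3 and SLC35B2 were higher by 3.43 and 3.26. ZC3H13, a subunit of the complex that writes the m6A mark on RNA, was higher by 2.73, CAMLG, of the insertion of tail-anchored proteins, by 2.72 and SRPR by 2.54. PCBP2 had -3.51, with 1.96 in Stable and -1.54 in UTP, and its call was lost without each outer library of UTP and Stable in turn.

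Between N1m and Stable the V-ATPase genes were again higher in the mRNA screen: ATP6AP1 by 5.28, ATP6V1B2 by 4.98, ATP6V0D1 by 4.74, ATP6V0C by 4.27 and ATP6V1A by 3.24. SLC35B2 was higher by 3.35, EXTL3 by 2.79 and NDST1 by 1.98. TRAPPC11 was higher by 3.25, CAMLG by 2.91 and ZC3H13 by 2.72. ATP6V1B2 and ATP6V0C passed in both interactions under every alternative and without each library in turn, though the differences of ATP6V1B2 ranged from 2.93 to 9.59 and from 2.72 to 8.40. EXTL3 also did so between UTP and Stable, and ATP6AP1 between N1m and Stable, and the other calls were lost in at least 1 of those settings. For PCBP2 and the pump and chain genes no technical explanation was tested here.

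TYW1B went from 2.54 in N1m to -2.88 in UTP on 2 guides, and the difference ranged from -9.23 to -2.70 over the alternatives and single libraries left out. The near copy TYW1 had 1.49 in the same interaction, as the mean over its guides. That argues against reads shared by the genes as a whole. It cannot exclude sharing by single guides, whose positions in the genome were not analysed. Noise of guides at a low level was also argued against, but for the outer bins and among genes with 2 guides only. In 1e+07 draws of pairs from other genes at the same unsorted level, 27 were as low. That gives 0.00074 genes expected among the 274 with 2 guides. TYW1B was picked as the only call among all 19026 genes, and this expectation does not cover the others. The second bins did not repeat the fall in UTP: TYW1B had -0.06 there, with replicates of -0.70 and 0.57, and 1.02 in N1m. Random pairs of non-targeting guides gave 0 such genes. But these guides are more abundant (median log2 level 4.83, well above that of TYW1B), so that test decides nothing. Each mRNA had its own screen, so other differences between the screens stay open too. A guide-specific effect and a real dependence on the modification may both remain open for TYW1B, whose call was lost with a pseudocount of 1/100 of the median, without a guide filter, with the median over guides, and without N1m top outer replicate 2, UTP bottom outer replicate 1 or UTP top outer replicate 2.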

How the results depend on the processing

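Summed whole reads with voom, the slope in the interactions and the test without UTP bottom second replicate 1 were chosen after seeing the data. Counts are given in the order N1m, UTP, Stable, and the cause was not tested for the counts and signs that moved. Over the planned and added alternatives, 66 counts of genes moved by more than 1.5 times and 66 did not, 2 counts of lists moved and 40 did not, and of the single genes 951 values kept direction and side of the threshold, 141 lost their call, 12 gained one and 8 changed sign. Read depth alone would leave 1.24% to 1.54% of guides at 0 in a sorted bin, where 4.78% to 8.09% were. The replicate spread implied 2.64 to 4.10 cells per guide, which would leave 11.1% to 18.2%, so the number of cells stays uncertain. Calls kept under every alternative and without each library were 8 of 21 in N1m (ATP6AP1, ATP6V0D1, ATP6V0C, ATP6V0B, SLC39A9, ATP6V1A, NDST1 and EXT2), 5 of 15 in UTP (ATP6AP1, ATP6V0C, ATP6AP2, EXTL3 and ATP6V1A) and 0 of 12 in Stable. Little sign of pairing by replicate number was seen: correlations between residuals of the same number were -0.0144 to 0.0390. The spread between sorted replicates would shrink such correlations, so weak pairing stays open. With the replicate block the outer-bin counts were 23, 18 and 10, the second-bin counts 20, 23 and 18, the top-bin counts against unsorted 6, 0 and 2, the bottom-bin counts 71, 72 and 105, and the interactions 1 (UTP minus N1m), 11 (UTP minus Stable) and 12 (N1m minus Stable). Robust rank aggregation gave 25, 22 and 8 genes in the outer bins, of which 19, 14 and 6 were the same genes. Rank aggregation was compared by these counts alone and is not among the alternatives under which single calls were kept or lost. The 4 outer libraries alone gave 21, 17 and 14, and voom gave 29, 19 and 13. Scaling to the same total tests nothing, since the values already share 1 total, and is left out of the counts of alternatives.

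With a pseudocount of 1/100 of the median the outer-bin counts were 13, 8 and 0, the second-bin counts 8, 6 and 5, the top-bin counts against unsorted 4 in N1m and 0 in Stable, and the bottom-bin counts 278, 118 and 294. The interactions gave 0 for UTP minus N1m, 3 for UTP minus Stable and 6 for N1m minus Stable. With 1/2 of the median the second-bin counts were 30 in N1m and 34 in UTP, the top-bin counts 1, 1 and 6, the bottom-bin counts 46, 32 and 35, N1m minus Stable gave 17, lists past the threshold in Stable were 2, KHNYN in UTP had 0.065 and ZC3HAV1 in Stable 0.0043.

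With no guide filter the counts were 2 in the Stable outer bins, 11 and 8 in the UTP and Stable second bins, 3 and 0 in the N1m and Stable top bins, 63 in the Stable bottom bin, 0 for UTP minus N1m, 7 for UTP minus Stable and 6 for N1m minus Stable. With a guide filter at 1/2 of the median they were 6 in the Stable outer bins, 4 and 0 in the N1m and Stable top bins, 47, 29 and 45 in the bottom bins, 0 for UTP minus N1m and 7 for UTP minus Stable, with 2 lists in Stable. With the median over guides they were 0 in the Stable outer bins, 9 and 6 in the N1m and Stable second bins, 2 and 0 in the N1m and Stable top bins, 33, 4 and 17 in the bottom bins, 0 for UTP minus N1m and 7 for UTP minus Stable, while KHNYN in UTP had 0.053.

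Centred on the non-targeting guides, the N1m top bin gave 4 and the bottom bins 33, 35 and 29, and KHNYN in UTP had 0.0020. The slope over the 4 bins gave 27 in UTP, 28 in Stable, 27 for UTP minus Stable and 17 for N1m minus Stable, with ZC3HAV1 at 0.16 in Stable. All 30 libraries in one fit gave 36, 34 and 2 in the outer bins. With no array weights the top bins gave 0 in N1m and 0 in Stable and the bottom bins 5, 3 and 0. With voom KHNYN in UTP had 0.35, and ZC3HAV1 and EXT1 in Stable had 0.13 and 0.073.

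Leaving out 1 library leaves its bin with 1 sample, which is assumed to vary like the others. The lowest and highest counts were 12 to 30 in N1m, 10 to 23 in UTP and 0 to 7 in Stable for the outer bins, 7 to 13, 8 to 96 and 7 to 16 for the second bins, 0 to 11, 0 to 0 and 0 to 0 for the top bins, and 1 to 199, 0 to 263 and 0 to 120 for the bottom bins. They were 0 to 1 for UTP minus N1m, 3 to 12 for UTP minus Stable and 4 to 17 for N1m minus Stable. Lists past the threshold numbered 3 to 3 in N1m, 3 to 4 in UTP, 1 to 2 in Stable, 0 to 0 for UTP minus N1m, 4 to 6 for UTP minus Stable and 3 to 4 for N1m minus Stable. Genes that changed sign ranged as follows in N1m: ZC3HAV1 from -0.12 to 0.81, KHNYN from -0.11 to 0.75, TRIM25 from -0.47 to 0.26 and MAVS from -1.61 to 0.50. In UTP KHNYN ranged from -0.22 to 0.22. In Stable the ranges were -0.15 to 1.99 for B4GALT7, -0.059 to 0.85 for EIF2AK2, -0.049 to 0.83 for DDX58, -0.14 to 0.086 for ZC3HAV1, -0.93 to 0.20 for N4BP1 and -1.13 to 0.053 for EXT1, and TRIM25 between UTP and Stable ranged from -2.00 to 0.29.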

Other observations

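The list tests here, the tests of TRIM25 with 1 guide left out and of the modification, and the test of scaling were chosen after results had been seen; the level-matched test of TRIM25 was added after that with non-targeting guides had been read. The list tests ask whether the members that did not pass moved with those that did, by camera with Benjamini-Hochberg adjustment over 54 tests.

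The complex that writes m6A on RNA, picked after the calls were seen, differed from Stable in the interactions of both mRNA screens. Those interactions share the Stable libraries, so they are not independent of each other. ZC3H13 passed in both interactions with Stable, with 1.21 in N1m, 1.22 in UTP and -1.51 in Stable. Its other 7 members all lay above 0 in the UTP minus Stable difference (median 0.90, adjusted p 0.00139), and 6 of 7 did in N1m minus Stable (median 1.48, adjusted p 0.000476). Both held with an estimated correlation, at adjusted p 0.0426. KIAA1429, now VIRMA, differed from Stable by 2.28 in UTP and 2.67 in N1m, RBM15 by 2.53 and 1.89, and METTL3 by 0.17 and 1.58, though none of these passed by itself in the outer bins. Over the slope of the 4 bins KIAA1429 passed in both (adjusted p 0.0139 and 0.0037). In the outer bins of single screens, where no member passed, the list of 8 had adjusted p-values of 0.00131 in N1m, 0.00251 in UTP and 0.00131, downward, in Stable, none of which held with an estimated correlation (0.261, 0.242 and 0.132). In the second bins ZC3H13 passed in N1m and UTP, with 2.02 (adjusted p 0.0293) and 1.87 (adjusted p 0.0257). The call on ZC3H13 was kept under 6 of 9 alternatives in each interaction with Stable. In UTP minus Stable it was lost without each outer library of UTP and Stable in turn, and the difference ranged from 1.97 to 3.32. In N1m minus Stable it was kept without 2 of 8 single libraries, and the difference ranged from 2.05 to 3.44. The screens hold no measure of m6A, and no mechanism was tested.

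Secretory complexes gave mixed results, with the other members past the threshold in 2 of 5 tests. For the signal recognition particle and translocon in UTP, where SRPR passed, the other 16 members had an adjusted p of 0.012 and a median of 0.26. For the COPI and COPII coats in N1m, where PREB passed, the other 22 members had 0.0257 and a median of 0.14. Neither held with an estimated correlation (0.218 and 0.261). For the GET pathway of tail-anchored proteins, where CAMLG passed, the other members had 0.138 in N1m and 0.886 in UTP, with a median of -0.04 in UTP, and for the TRAPP tethers in N1m they had 0.171. Members of these lists went both ways, so whether any moved with the called genes stays open.

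Chromatin complexes were tested the same way in Stable. The other members of the menin and KMT2 complexes, beyond MEN1, KMT2A and KMT2C, had an adjusted p of 0.046 (0.261 with an estimated correlation). The other members of the BAF complexes had 0.801, and those of the NuA4 complex of KAT5 had 0.0746. For the NuRD complex of CHD4 they had 0.863 with a median of -0.04 and went both ways, which leaves open whether any moved with CHD4. The call on CHD4 itself was kept under 5 of 11 alternatives and without 1 of 4 single libraries. One untested reading, which may be checked with another reporter, is that menin and KMT2 proteins keep the GFP gene on. No call in Stable was kept under every alternative and without each library in turn.

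TRIM25 in the UTP screen fell over the bins in the mean of the replicates, without passing in the outer-bin contrast, though replicate 2 read 4.03 RPM in the bottom second bin and 8.19 RPM in the bottom outer bin. A single guide as the cause was argued against, since the difference was -1.94 or further below 0 with any of its guides left out. Noise of guides at this level was argued against too, but for the slope alone, since no level-matched draws were made for the outer-bin difference. Of 1e+07 draws of 4 guides of other genes, 7 had a slope as low, which gives 0.0133 genes expected among 19026. Sets of 4 non-targeting guides gave 0, with an upper bound of 0.0057, but decide nothing because those guides are more abundant (median log2 level 4.83 against 3.18). The modification of the mRNA may be the cause, and stays open. Each mRNA had its own screen, so the modification cannot be told apart from other differences between the screens. The UTP minus N1m difference was -2.58 ± 0.89 by limma (adjusted p 0.9998). But TRIM25 also had -1.83 in Stable, with 4 of 4 guides negative, and UTP minus Stable was -0.86 (adjusted p 0.996). The guide furthest below 0 in Stable, picked after its values were seen, had -3.73 there but -0.21 in UTP. Without that guide the difference was -1.20 in Stable, -3.52 in UTP and -0.08 in N1m. With any guide left out Stable stayed at -1.20 or further below 0, so it did not rest on a single guide either.

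Lower calls in the bottom bin against unsorted cells numbered 90, 61 and 93 in N1m, UTP and Stable, but 0 in each with no array weights or without either unsorted library. Here 0 genes were lower in more than 1 screen, where draws matched on unsorted level gave 1.02 on average. With so few expected by chance, the overlap cannot decide whether a property of the genes was shared by the screens. Few cells per guide could produce the lower calls, which stays open. The summed RPM of the non-targeting guides in the bottom bin was 0.974, 0.965 and 0.969 of that in unsorted cells. Their mean log2 difference was -0.205, -0.224 and -0.185, as when some guides drop out and others grow. But any wider spread of guides at a similar sum lowers the mean log2, so these values cannot single out few cells. The replicate spread implied 2.64 to 4.10 cells per guide in sorted bins against 29.1 to 34.0 in unsorted cells, but so few cells would leave 11.1% to 18.2% of guides at 0 in a sorted bin, where 4.78% to 8.09% were, so these numbers do not describe the cells well. Scaling of the libraries stays open, since centring on the non-targeting guides left 18, 22 and 27 of the lower calls, 67 in all.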
